A study of Mus musculus with 2 samples.

How the data were processed

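Total RNA from the eye cups of mice at postnatal day 13 was profiled on Affymetrix Mouse 430 2.0 arrays, which read each transcript through probe sets placed mostly near its 3' end. Per the labels, equal amounts of RNA from 6 animals were pooled for each genotype, and each pool was hybridised to 1 array, so that the series holds 2 arrays in all. An eye cup is the back of the eye (retina, pigment epithelium, choroid and sclera) that remains after the front is cut away. The labels' protocols say that cornea, lens and optic nerve were taken off and the tissue was frozen at once. They do not say which part of Mfsd2a is deleted, which strain the mice were, or how many males and females entered each pool.

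The values deposited by the authors are intensities on a linear scale, 1 for each of 45101 probe sets on each array. Per the submitters' processing notes, Partek 6.6 and RMA (robust multi-array averaging, a method that corrects background, equalises the distributions of arrays and combines the probes of a set) were used, with no order or settings given in the sources used here. The linear scale was read from the values, which ran from 5.15 to 20644 on the wild-type array and from 5.07 to 20568 on the other. Their medians were 94.4 and 93.6. The values had not been centred. Scanner files, detection calls and scan dates were not used here, so it is not known whether the 2 arrays were processed on the same day. RMA shrinks differences of dim probe sets, and its equalising step removes any overall difference between the pools.

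Base 2 logarithms were taken, and each difference is the array labelled knockout minus the wild-type array. Of the 45101 probe sets, 34958 carried 1 gene symbol in the platform annotation, 932 carried several and 9211 none, of which 51 were controls. An Entrez identifier in the RefSeq gene table of assembly GRCm38.p6 was found for 34754 of the probe sets with 1 symbol. For the other 204 the annotation's symbol was kept, and the table changed 0 symbols. Each of 18193 genes took the probe set with the highest mean of the 2 arrays among those with that symbol alone. A gene counted as measured when the higher of its 2 values reached that array's median over probe sets other than the 64 Affymetrix controls, which was 94.2 on the wild-type array and 93.4 on the other. This left 11568 genes. Chromosomal order, with no coordinates, came from the same RefSeq table.

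With 1 array per genotype there is no spread between samples, so no test of a gene was made and no p-value is given. The number of arrays limits the precision of every value. Genes were counted by a fixed size of difference, 1.5-fold. The only error that could be computed was technical: the SD of the log2 differences of probe sets for the same gene was 0.0886, and 9183 genes had only 1 probe set. Among 5201 measured genes with at least 2 probe sets above the floor, 2369 had probe sets of both signs.

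The text names Mfsd2a, then the 12 genes with the largest positive and the 12 with the largest negative differences among measured genes whose probe sets above the floor share a sign, leaving out symbols that are only clone names. It also draws on up to 4 members of each gene list with the largest absolute difference and the first 4 measured members in the order of the list. The 38 gene lists covered retinal cell types, the other tissues of the eye, immune cells, vessels, lipid metabolism, stress and housekeeping programs, and sex-linked transcripts, and they were written from general knowledge. Each list's median was placed among the medians of 10000 random lists of as many measured genes, matched on mean level in 20 bins. The percentile and the central 95% of those medians describe these libraries and are not a test of genotype. By chance 1.9 of the 38 lists would lie outside. Members of a list are often expressed together, which random lists do not copy, so their range is narrower than that of a true list of related genes. Of 793 different measured genes in the lists, 35 stood in more than 1.

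The gene lists, the named-gene rule, the 1.5-fold size and most alternatives were fixed before the data were examined. The alternatives were sizes of 2-fold and 1.3-fold, no floor, a floor at the 70th percentile, the mean of a gene's probe sets, leaving out probe sets whose names mark possible cross-hybridisation (ending in _s_at or _x_at), and removing a loess trend of the difference on the mean level (span 0.3, 3 robustifying iterations). Added after seeing the data were counts without the genes of the lens, muscle, cornea, myelin and sex lists, and the probe set with the largest difference in place of the brightest. A further list, of retinal progenitors and newborn neurons, was also added after the first results.

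The steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. They were tested on simulated data made from the 11568 measured genes of the knockout minus wild type comparison. Of 50 genes given a log2 difference of 0.4 on top of their own, 5 passed the 1.5-fold rule, as did 48 of 50 given 0.8, 50 of 50 given 1.2 and 50 of 50 given 2.0. Of 100 random lists of 20 genes left alone, 4 lay outside the central 95%, and 100 of 100 lists raised by 0.1 lay above it.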

Results

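Mfsd2a encodes a membrane transporter that carries lysophosphatidylcholine with docosahexaenoic acid and other long fatty acids into brain and eye. The series set the gene expression of Mfsd2a knockout eye cups beside that of wild-type eye cups at postnatal day 13, about when mouse pups open their eyes. Each genotype was 1 array of RNA pooled from 6 animals. Every value below is a single intensity with no replicate, so a difference between the arrays is a difference between 2 pools and carries no p-value. Over the 11568 measured genes the log2 values of the arrays had a Pearson correlation across genes of 0.997, where genes are not independent replicates. The median log2 difference was 0.014, and the central 95% of genes lay between -0.21 and 0.23.

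The deleted gene was examined first, as a check of the labels. Its 1 probe set read 181 on the wild-type array and 244 on the array labelled knockout, a log2 difference of 0.43 or 1.35-fold higher. This is against the direction a knockout label gives. The labels do not say which part of the gene is deleted, and where the probes lie relative to that part was not analysed here, so a probe set outside the deletion would check nothing. For this reason the second sample is called the array labelled knockout throughout, and each direction given here rests on that label.

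At the 1.5-fold size, 16 measured genes were higher and 10 were lower on the array labelled knockout. The counts were 6 and 4 with the floor at the 70th percentile, and 21 genes were lower with no floor. At 2-fold, 4 were higher (Scd1, Mycl, Trit1 and Uty) and 0 were lower. These counts take the brightest probe set of each gene: for Mbp, the myelin basic protein gene, that set differed by 0.14, while 5 of its 8 probe sets were at least 2-fold lower, 4 of them above the floor. The smaller size of 1.2-fold gave 207 higher and 135 lower. Between the pools, sex-linked transcripts differed too: the 3 measured Y-linked genes, Uty (log2 difference 1.01), Kdm5d (0.88) and Eif2s3y (0.65), had a median of 0.88, at percentile 100 of random lists. It was 0.45 with no floor and 0.42 with the mean of probe sets, where 1 member was measured. Xist, the noncoding RNA of the inactive X chromosome in females and the 1 measured member of the female list, read 7055 on the wild-type array and 4357 on the other, a log2 difference of -0.70 at percentile 0.065. Its 3 probe sets ran from -0.98 to -0.70, and with no floor the median of the 2 members of the list was -0.38.

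**Figure D1:**
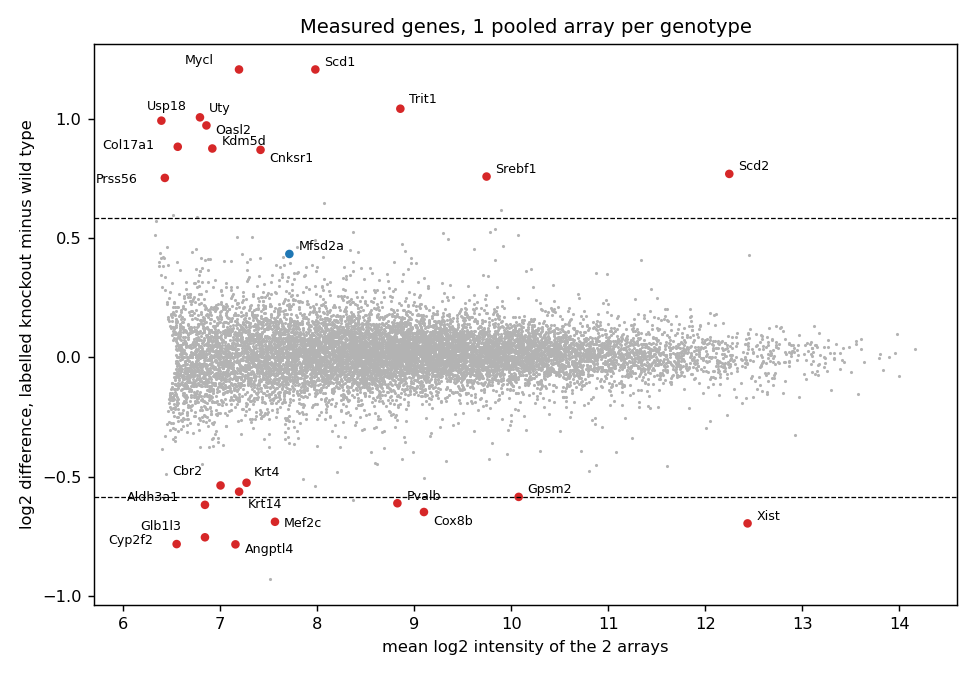
Log2 difference (array labelled knockout minus wild type, vertical) against mean log2 intensity (horizontal) for the 11568 measured genes, 1 point per gene from 1 pooled array per genotype. Dashed lines mark 1.5-fold, red points are the 12 named genes with the largest difference in each direction, and Mfsd2a (blue) lies at 0.43.

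Genes of lipid synthesis were higher on the array labelled knockout. Scd1, a desaturase that makes monounsaturated fatty acids, read 166 in wild type and 384 in the other pool (2.31-fold), although its dimmer probe set, below the floor, differed by 0.43. Its relative Scd2 read 3727 and 6351 (1.70-fold), with 3 probe sets between 0.77 and 0.86. Srebf1, which encodes the transcription factor SREBP1 that drives fatty acid synthesis, read 661 and 1117 (1.69-fold). In the list of fatty acid synthesis and SREBP1 targets, 18 of 23 measured members were above 0, 8 were at least 1.2-fold higher and 3 at least 1.5-fold, with a median log2 difference of 0.13 at percentile 100. Fads1 (0.52) and Fads2 (0.45), the desaturases on the path to polyunsaturated fatty acids, and Fasn (0.35), the fatty acid synthase, were among them, while Acly differed by 0.044.

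All 21 measured members of the list of cholesterol synthesis and SREBP2 targets were above 0, and 10 were at least 1.2-fold higher. Their median was 0.25, at percentile 100. Examples were Lss (0.53) and Dhcr7 (0.50), enzymes late in the sterol path, Insig1 (0.52), a sterol-responsive regulator of the SREBP proteins, and Cyp51 (0.35). The list of polyunsaturated fatty acid supply and phospholipid remodelling had a median of 0.057 at percentile 99.8, with 23 of 39 members above 0. It held Fads1 and Fads2 as well as Rbp3 (0.43), the retinoid carrier between photoreceptors and pigment epithelium, and Acsl4 (0.37). With the mean of a gene's probe sets that median was 0.0033. Liver X receptor targets, a list that shares Scd1, Scd2 and Srebf1, its 3 genes past 1.5-fold, with the fatty acid synthesis list, had a median of 0.060, inside the central 95% at percentile 96.0, with 8 of 13 above 0. With no floor it lay above, at percentile 97.7. Apoc1 differed by 0.45 and Abca1 by 0.24.

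Genes of fatty acid oxidation and PPAR targets went the other way, with 22 of 30 measured members below 0 and a median of -0.074 at percentile 0. Angptl4, a PPAR target that inhibits lipoprotein lipase, read 187 in wild type and 109 in the other pool, a log2 difference of -0.78. That value came from a probe set whose name marks possible cross-hybridisation, and the other probe set, below the floor, differed by 0.046. The mitochondrial enzymes Acadl (-0.32) and Acaa2 (-0.29) were at least 1.2-fold lower. Lens genes, given with the other tissues, were higher in the same pool as the synthesis genes, as were the Y-linked genes. Skeletal muscle genes were lower in the same pool as the oxidation genes, with a median of -0.15.

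**Figure D2:**
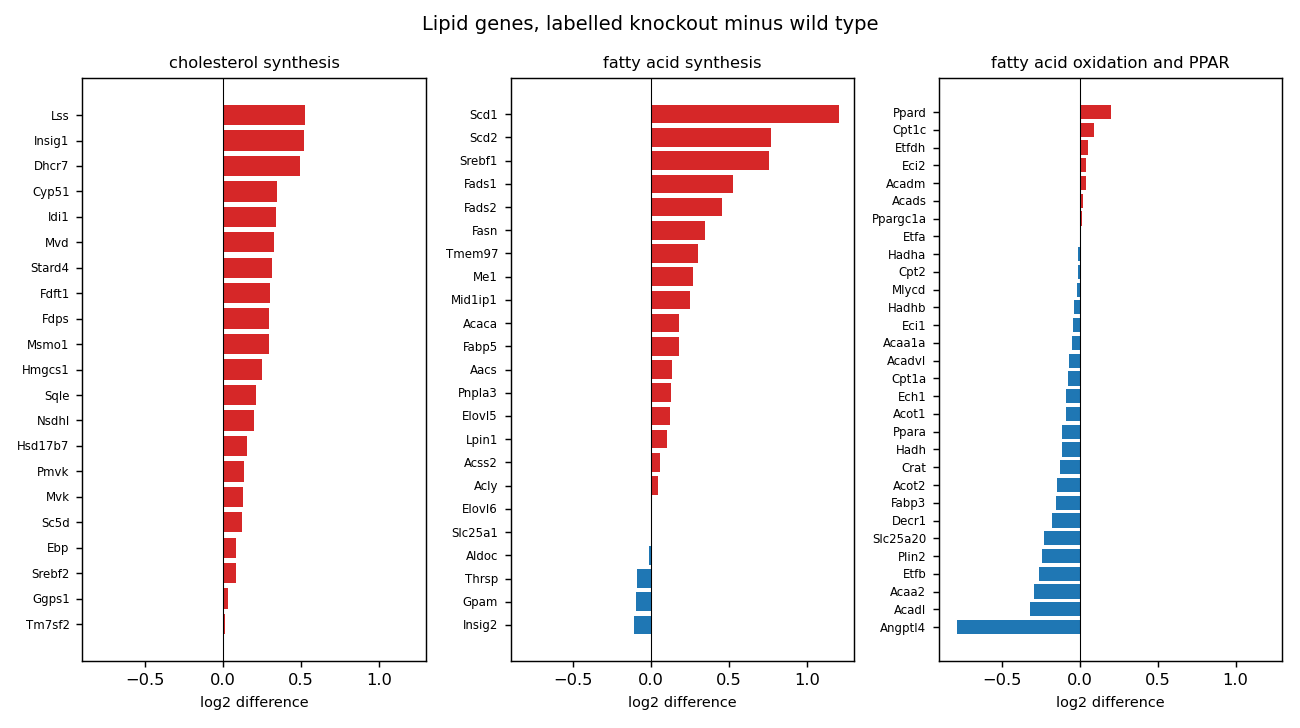
Log2 difference (array labelled knockout minus wild type) of each measured member of 3 gene lists, 1 bar per gene. All 21 cholesterol genes lie above 0 and 22 of the 30 fatty acid oxidation genes lie below.

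Next to Mfsd2a on its chromosome, 2 further genes were more than 2-fold higher. Mycl, a transcription factor of the Myc family, read 96.5 in wild type and 223 in the array labelled knockout (2.31-fold), and Trit1, a transfer RNA modifying enzyme, read 323 and 666 (2.06-fold). They are the nearest measured genes on one side. Of the 50 measured genes on each side of Mfsd2a, these were the 2 past 1.5-fold, or 2% of 100 genes against 0.225% of all measured genes. The other 16 genes nearest to it differed by between -0.072 and 0.23. The remaining 2 probe sets of Mycl lay below the floor and differed by 0.48 and 0.55.

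**Figure D3:**
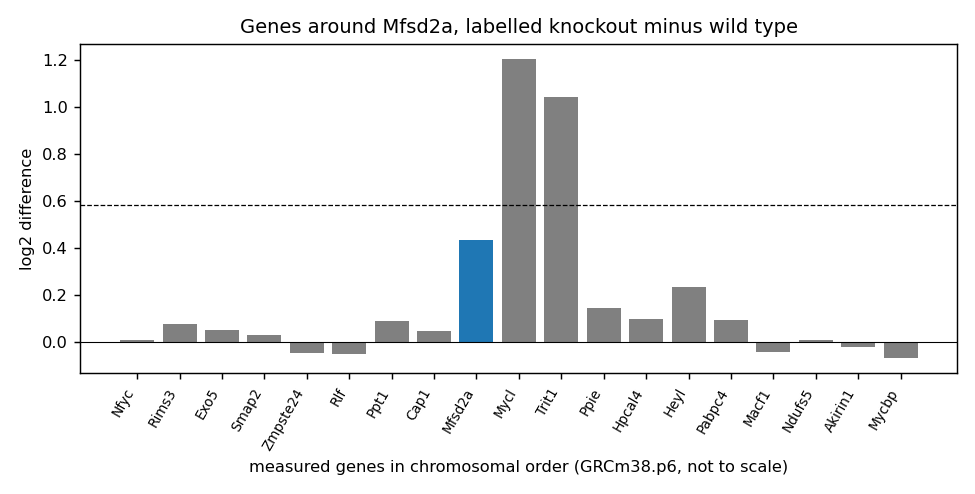
Log2 difference (array labelled knockout minus wild type) of Mfsd2a (blue) and of measured genes around it in chromosomal order, 1 bar per gene, not drawn to scale. Mfsd2a, Mycl and Trit1 stand side by side at 0.43, 1.21 and 1.04, and the other 16 genes lie between -0.072 and 0.23.

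Transcripts of microglia, the resident macrophages of the retina, were higher on the array labelled knockout. Of 19 measured members of the microglia and macrophage list, 15 were above 0 and 8 were at least 1.2-fold higher, with a median of 0.25 at percentile 100. They included the complement gene C1qa (278 and 379, log2 difference 0.45), Cd52 (0.42), the fractalkine receptor Cx3cr1 (0.41) and the signalling adaptor Tyrobp (0.39). Other microglial genes differed little, with Csf1r at 0.024 and Tmem119 at -0.078. Interferon response genes had a median of 0.26, also at percentile 100, with 16 of 17 above 0. Usp18 (59.7 and 119, 1.99-fold) and Oasl2 (82.9 and 163, 1.96-fold) led them, both below the floor in wild type, followed by Rtp4 (0.43) and Irf7 (0.41). Only 2 interferon genes reached the higher floor at the 70th percentile, where their median was -0.0089. The gliosis and retinal stress list had a median of 0.030, inside its range at percentile 71.7, with Egr1 at 0.47 and Cd44 at 0.30. Only 15 of its 27 genes were measured, and Gfap, Serpina3n and Lcn2, which head it, were not among them. The list lay above its range with no floor (0.090 over 25 genes) and at the higher floor (0.11). Its median was -0.018 with the mean of probe sets. Mueller glia, the main glia of the retina, had a median of 0.015 at percentile 59.5, although Crym differed by 0.41. Erythroid genes, as a marker of blood, had a median of -0.037 over 5 members at percentile 16.2.

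Photoreceptor genes were slightly lower. The rod list had a median of -0.025 at percentile 0.86, with 23 of 32 members below 0, and a median of -0.043 with the mean of probe sets. The largest differences were in Guca1a (3663 and 2671, -0.46) and Guca1b (-0.33), calcium sensors of phototransduction, and in Grk1 (-0.33), the rhodopsin kinase, while the rod transducin gene Gnat1 differed by -0.079. Cone genes had a median of -0.039 at percentile 2.42, with 9 of 15 below 0 and Opn1mw, the medium wavelength opsin, at -0.28. This median lay inside its random lists once the loess trend was removed. The list of cilium and outer-segment transport was inside at 0.016 (percentile 55.8), with Cep290 at 0.29.

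Among the inner retinal neurons, ganglion cell genes were lower, with 14 of 18 below 0 and a median of -0.10 at percentile 0. Nefh, a heavy neurofilament, differed by -0.39 and Slc17a6, a vesicular glutamate transporter, by -0.24, or -0.059 in its other probe set. Rbpms differed by only -0.060, and Pou4f1 was slightly higher (0.076). Bipolar cells had a median of 0.015 (percentile 57.0), amacrine cells -0.0090 (percentile 13.0) and horizontal cells 0 (percentile 34.1), all inside their ranges, except that the amacrine median was below with the mean of probe sets (-0.033). Mef2c, a transcription factor of neurons and muscle, was lower in all 4 of its probe sets above the floor, by -0.69 to -0.52, and Gpsm2 read 1323 and 883 (-0.58).

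Genes of pigment epithelium and pigment cells were lower as well. The list of retinal pigment epithelium and visual cycle had 24 of 34 members below 0 and a median of -0.053 at percentile 0. Its largest differences were Aqp1, a water channel (-0.36), and the visual cycle genes Rdh5 (-0.34), Lrat (-0.31) and Rgr (-0.30), whereas Rpe65 differed by -0.078. For melanin synthesis and pigment cells 19 of 20 members were below 0, with a median of -0.13 at percentile 0 and Mlana at -0.28. In the vessels, the endothelium and blood-retina barrier list had 25 of 34 members below 0 and a median of -0.056 at percentile 0.02, or -0.088 with the mean of probe sets. Slco1c1, a thyroid hormone transporter of barrier endothelium, read 458 and 336 (-0.45), and Cldn5, a tight junction protein, differed by -0.21. The pericyte and smooth muscle list had a median of -0.088 at percentile 0.11, with 11 of 13 below 0, and was -0.15 at the higher floor and -0.14 with the mean of probe sets. The hypoxia and glycolysis list had 21 of 25 below 0, a median of -0.057 at percentile 0 and Hk2, a hexokinase, at -0.44.

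Some gene lists written for tissues that border the eye cup also differed between the pools, beside all of the groups above. Lens genes were higher on the array labelled knockout, with 11 of 14 above 0 and a median of 0.21 at percentile 100. The crystallins Cryga (0.40), Crygf (0.38) and Cryaa (0.35) led them. Cornea and conjunctiva genes were lower in all 14 measured members, with a median of -0.17 at percentile 0, led by Aldh3a1 (-0.62), Krt14 (-0.56) and Krt4 (-0.53). At the higher floor their median was -0.063 over 7 genes. Skeletal muscle genes had 13 of 19 members below 0 and a median of -0.15 at percentile 0, or -0.077 over 35 genes with no floor. Pvalb (561 and 368, -0.61) and Ckm (-0.34) were lower, whereas the muscle actin Acta1 (0.029) and the myosin Myh1 (0.22) were not. Sclera and choroid connective tissue (median -0.015, percentile 3.63), ciliary body and iris (-0.016, percentile 13.7) and myelin and oligodendrocytes (-0.043 over 6 genes, percentile 6.3) lay inside their ranges. The sclera median was below its range in 4 of the 5 alternatives, at -0.029 to -0.035, and the myelin median with no floor (-0.13) and with the mean of probe sets (-0.095). Further genes among those with the largest differences were Col17a1 (0.88), Cnksr1 (0.87) and Prss56 (0.75) on the higher side and Cyp2f2 (-0.78), Glb1l3 (-0.75), Cox8b (-0.65) and Cbr2 (-0.54) on the lower side. Col17a1 and Prss56 lay under the floor in wild type, and Cyp2f2, Glb1l3 and Aldh3a1 on the other array, so the sizes of their differences are less certain.

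**Figure D4:**
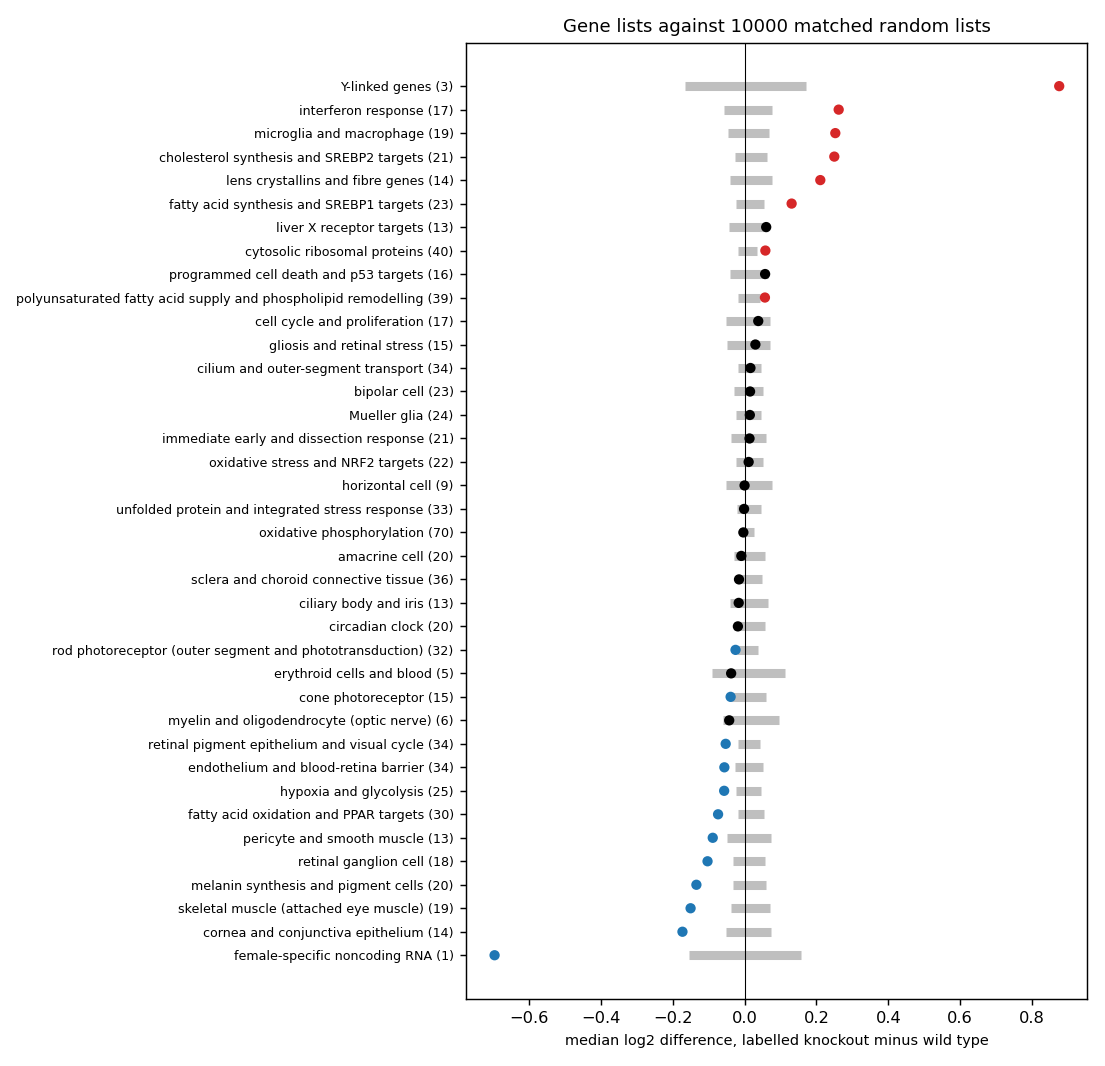
Median log2 difference (array labelled knockout minus wild type) of the measured members of each of 38 gene lists, with the number measured in brackets. Grey bars span the central 95% of 10000 random lists matched on level, and points are red for the 8 lists above it, blue for the 12 below and black for the 18 inside.

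Of the general cell programs, cytosolic ribosomal proteins were higher by a small amount, with 38 of 40 above 0 and a median of 0.058 at percentile 100. Rplp0 differed by 0.13. Inside their ranges lay oxidative phosphorylation (-0.0034 over 70 genes, percentile 10.6), the unfolded protein and integrated stress response (-0.0013, percentile 18.4), oxidative stress and NRF2 targets (0.011, percentile 43.6) and cell cycle and proliferation (0.038, percentile 82.6). So did programmed cell death and p53 targets (0.057, percentile 95.2), the circadian clock (-0.019, percentile 7.96) and immediate early genes (0.014, percentile 53.2), of which Ccn1 differed by 0.59 and Nr4a1 by 0.47.

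In all, 8 of the 38 lists lay above the central 95% of their random lists, 12 below and 18 inside, where chance gives 1.9 outside. Medians of the lists inside lie near 0, and several moved by over 1.5 times or changed sign under the alternatives. With the mean of probe sets some named genes differed by less, among them Mycl (0.75), Angptl4 (-0.37), Krt14 (-0.37), Eif2s3y (0.42), Kdm5d (0.23), Lss (0.23), Ccn1 (0.23), Rtp4 (0.22), Cx3cr1 (0.21), Acadl (-0.20), Slc17a6 (-0.15), Cd44 (0.14) and Ckm (-0.11). The 3' to 5' signal ratio, a measure of RNA integrity, was 1.49 in wild type and 1.44 in the other array for beta-actin, 0.973 and 0.942 for Gapdh, 3.07 and 2.93 for transferrin receptor and 3.94 and 3.98 for pyruvate carboxylase. Of 18 hybridisation spike-in probe sets 17 were above 0, with a median difference of 0.099, and 24 labelling spike-in probe sets ran from -0.18 to 0.33 with a median of 0.046. These technical differences are as large in size as several list medians, such as those of rods, pigment epithelium and ribosomal proteins. With 1 pool per genotype, genotype, sex make-up, dissection and array handling cannot be told apart.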

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

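Data outside the gene comparisons, the probe sets with no gene symbol in the annotation used, also differed between the arrays. Above the floor, 2264 unnamed probe sets were read, of which 5 were at least 1.5-fold higher and 7 at least 1.5-fold lower on the array labelled knockout. The highest difference among the unnamed was 1.08 on the log2 scale, with an intensity of 242 in wild type and 513 in the other array. Another probe set read 314 and 619. On the lower side, one read 324 and 149 (-1.12) and another 834 and 486 (-0.78). These were singled out after their values were seen, and no explanation was tested for them.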

How the results depend on the processing

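No paired analysis was possible because each genotype is 1 pool. The cause of each change below was not tested, apart from the fewer genes a higher floor leaves. The counts of 16 higher and 10 lower genes became 4 and 0 at 2-fold, 74 and 36 at 1.3-fold, and 6 and 4 with the floor at the 70th percentile. With no floor 21 genes were lower. The 16 and 10 genes kept their side in all cases with no floor and with the loess trend removed. Of them 6 and 4 were kept at the higher floor, 10 and 7 with the mean of probe sets, and 14 and 9 without _s_at and _x_at probe sets. Part of this was fixed in advance. The floor does not alter which probe set of a gene is brightest, so removing it could lose none of these genes. A gene with 1 probe set, such as Trit1, Srebf1 or Cox8b, cannot change with the mean. Without _s_at and _x_at probe sets, only genes read by such a set could change. Additions chosen after seeing the data, leaving out the tissue and sex list genes (13 higher and 7 lower) and taking the probe set with the largest difference (22 and 12), moved neither count by over 1.5 times. Among lists outside their ranges and named genes past 1.5-fold, the sign changed for the interferon list at the higher floor (-0.0089) and for Angptl4 without _s_at and _x_at probe sets (0.046). Medians near 0 of lists inside their ranges changed sign as well, among them gliosis, erythroid, circadian, Mueller glia and cilium in the values below.

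Of the lists, 6 of the 8 above their random lists stayed above in all 5 alternatives that recomputed every list, 11 of 12 stayed below and 13 of 18 stayed inside. The interferon list came inside at the higher floor, polyunsaturated fatty acid supply with the mean of probe sets and cones with loess. Gliosis lay above with no floor and at the higher floor, liver X receptor targets with no floor. Below lay sclera in 4 of the 5, myelin with no floor and the mean of probe sets, and amacrine with the mean. Medians that moved by more than their spread follow. With the mean of probe sets they were rod -0.043, amacrine -0.033, gliosis -0.018, interferon 0.23, endothelium -0.088, pericyte -0.14, muscle -0.12, lens 0.18, cornea -0.13, myelin -0.095, erythroid 0.014, cholesterol 0.21, polyunsaturated fatty acid supply 0.0033, fatty acid oxidation -0.055, cell death 0.024, circadian 0.015, Y-linked 0.42 and female -0.88. With no floor they were Mueller glia -0.0089, gliosis 0.090, microglia 0.20, interferon 0.18, muscle -0.077, lens 0.14, myelin -0.13, cell cycle 0, cell death 0.020, Y-linked 0.45 and female -0.38. At the higher floor they were gliosis 0.11, microglia 0.30, pericyte -0.15, cornea -0.063, cholesterol 0.27, hypoxia -0.076, immediate early 0.049 and Y-linked 0.65. Without _s_at and _x_at probe sets they were pericyte -0.12, sclera -0.035, cornea -0.21 and female -0.96. With the loess trend removed they were cilium -0.0016, pigment epithelium -0.072, sclera -0.035, polyunsaturated fatty acid supply 0.038, unfolded protein -0.020 and oxidative phosphorylation -0.016. The myelin median was -0.097 with the probe set of largest difference. Of 265 named genes, 265 moved by less than the spread between probe sets with the loess trend removed and 215 with the mean of probe sets. Without _s_at and _x_at probe sets 247 did so, 15 moved by more, Angptl4 changed sign and 2 had no value. Among the 15, Tfap2c also changed sign, from 0.25 to -0.19. Some named genes with smaller differences also changed sign under an alternative, such as Tfap2c, Col12a1 and Hells with the mean of probe sets. Signal over background limits the dim genes, among them Usp18, Oasl2, Uty, Kdm5d, Col17a1, Prss56, Ccn1, Cd52, Apoc1 and Neurog2, under the floor in wild type, and Cyp2f2, Glb1l3 and Aldh3a1, under it on the other array.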

Other observations

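Of the tests in this part, those of the loess trend, of a stretch of another strain's DNA and of the less mature retina were written before their results were seen, and the others were chosen after. Among these, the lens test was altered after its first result: it was given a second part for the cholesterol genes, and genes found only in lens were then required before lens was excluded. The myelin test first used Mbp and the chance test first used runs of 3 genes. Both had gone against their explanation, and both were replaced by the list and the window fixed before the data were examined, because the first forms rested on genes picked for their values. A test of a faulty probe set was dropped, because it ran on the genes that define its pattern or on Mycl probe sets below the floor.

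Mbp, the main protein gene of myelin, was singled out after its values were seen. Of its 8 probe sets, 6 were at least 1.5-fold lower on the array labelled knockout, by log2 differences of -0.74 to -2.00 (one of these, at -1.37, lies below the floor), and the other two, one of them the brightest and so the one used for the gene, differed by 0.098 and 0.14. The brightest of the 6 read 574 in wild type and 171 in the other array. Further myelin genes lay below the floor, with Mag at -0.34 and Olig1 at -0.54, and the 2 probe sets of Mal, a gene outside the list, differed by -0.42 and -0.38. Other measured members of the list differed little, with Ermn at 0.019, Sox10 at -0.012 and Cnp at -0.073.

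A few genes of late retinal development, picked after their values were seen, were higher. Insm1, a transcription factor of newborn neurons, differed by 0.51 and 0.62 in its 2 probe sets, the photoreceptor fate gene Prdm1 by 0.42, Neurog2 by 0.39 and the tubulin gene Tubb2b by 0.54. A less mature retina in the pool labelled knockout may account for this. A list of 34 other genes of retinal progenitors and newborn neurons was written after the first results but before its median was read. Some members, such as Hes1, Lhx2 and Ccnd1, also stood in the earlier lists, so the list was not wholly unseen. Its median was 0.046 over 28 measured members, at percentile 95.9 and within the central range of -0.026 to 0.049. The test leaves the hypothesis open.

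The higher sterol and fatty acid synthesis genes could come from technical differences between the pools. Removing the loess trend of difference on level took the median of the cholesterol genes from 0.25 to 0.24, so that trend is small beside it. This median stayed above its random lists. Those lists were already matched on level, so their comparison adds little about such a trend. More myelin in the pool was not decided by the median of the myelin list, -0.043 and inside its range. Further values argue against more myelin, for the genes of that list. Its highest measured member differed by 0.14. The list's median fell below its range with no floor (-0.13) and with the mean of probe sets (-0.095). More lens could not be decided: the highest lens gene differed by 0.40 against 0.76 for the lowest of Scd1, Scd2 and Srebf1, but crystallins are also made in retina and the lens genes Lim2 and Mip lie below the floor, and the lens median of 0.21 lies close to the 0.25 of the cholesterol genes. More males in the pool stays open because pool and genotype are the same, with Xist at -0.70. Genotype itself stays open beside these and was not tested.

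Mfsd2a, Mycl and Trit1 stand side by side and are all higher. A count of 2 neighbours past 1.5-fold was uncommon elsewhere. Of 9339 windows of 50 measured genes on each side of another gene, 170 or 1.82% held as many, and the most was 3. Windows overlap, so they are not independent. The 2 genes counted, Mycl and Trit1, are also those that define the pattern, so chance placement is not excluded. A stretch of another strain's DNA around the gene could not be decided: 5 of the 98 other neighbours differed by at least 1.2-fold, where runs of as many genes elsewhere had a median of 3 and a 95th percentile of 6. No biological explanation was tested.

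Microglia genes were higher while the genes of most other cell types were not. A smaller share of the main retinal cells alone would raise the markers of other types alike, but 6 of 9 lists of other cell types lay below their random lists. The lists of pigment epithelium (-0.053), endothelium (-0.056) and pericytes (-0.088) were lower, while the lens list was higher (0.21). The rod list was itself lower (-0.025), as a smaller share of rods would give. The test was written after these medians were seen, so the explanation is not excluded. More blood in the pool could not be decided, with an erythroid median of -0.037 over 5 genes. Whether more microglia or more of these transcripts per cell lies behind the difference was not tested, and sex and dissection of the pools remain open for it.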
